A study of Rattus norvegicus with 32 samples.

How the data were processed

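Total RNA from rat liver was measured on 32 single-colour Affymetrix rat arrays. Per the labels' protocols, RNA was purified on QIAGEN columns with a DNase step, its quality was checked on an Agilent Bioanalyser, and biotin-labelled cRNA was hybridised. The deposited values are probe-set intensities on a linear scale, between 30.5 and 15558 with no missing value, which the authors summarised with PLIER in Affymetrix Expression Console, per the submitters' processing notes. The versions of both tools are not given in the sources used here, nor are the background correction and the scaling between arrays. Array medians lay between 147 and 161, and no further scaling was applied to the reported results. Detection calls, scan dates and hybridisation batches were not used here. Probes for nonspecific binding read 54.3 to 92.0 units (array medians), so background signal remains in the values and the fold changes of dim genes are understated.

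Each sample's group and replicate number came from its title, which gives the exposure and harvest time. There were 6 air and 6 ozone arrays at the end of exposure on day 1, 5 and 5 at the end of day 2, and 5 and 5 at 18 h after day 2. Pairs of arrays correlated between 0.965 and 0.997, with no identical pair, so every array counted as 1 replicate. No array was left out of the reported results, and no sample was moved to another group.

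The value table held 31139 probe sets. Control probe sets (97), probe sets without a gene in the platform annotation (11407) and probe sets with several genes (573) were left out of the gene-level tests, which leaves 19062 probe sets with 1 gene and 13437 genes. Entrez identifiers of 18983 of these probe sets were found in the RefSeq gene table, and 0 symbols needed an update. Probe sets whose mean log2 value lay below the 25th percentile were left out, and the brightest remaining probe set stood for its gene, which left 11625 genes. Values were analysed as log2(intensity + 16), so every log2 difference is on that scale. The design written before the data were examined foresaw log2 values, or this offset if the values were linear, as they turned out to be.

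Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in 1 model with a mean for each of the 6 groups and no block, so that all arrays shared 1 estimate of the spread. Contrasts were ozone minus air at each harvest time, the difference between consecutive ozone effects, and air at 18 h after day 2 minus air at the end of day 2. All p-values are two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Errors of log2 differences are standard errors from limma, and errors of group levels are SD. Counts expected at 2 times for independent lists are the product of both counts over the genes tested. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

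A total of 29 gene lists, 8 of them markers of other cell types and tissues, were written from general knowledge before the data were examined. They cover glucocorticoid response, gluconeogenesis, glycolysis, amino acid catabolism, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, bile acids, acute phase, NRF2 targets, metallothioneins, heat shock, integrated stress response, circadian clock, xenobiotic enzymes, growth hormone targets, immediate early genes, cell cycle, oxidative phosphorylation, interferon response and ribosomal proteins. The marker lists cover Kupffer cells, neutrophils and monocytes, lymphocytes, stellate cells, endothelium, cholangiocytes, erythroid cells, and pancreas and adipose tissue. Some genes stand in several lists, so the list results are not all separate. Lists with at least 4 tested members were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members of that list. The list scores in the closing section are means of the members' log2 values centred on the mean of all arrays, compared by exact permutation tests.

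The genes named were set by a rule, also fixed before the data were examined. From each contrast came the 5 largest rises and the 5 largest falls past the threshold, with unannotated loci (LOC and RGD names) passed over. In ozone minus air and air contrasts, every array of the first group also had to lie on the same side of the reference mean. From each list came the 2 members with the smallest p, or 4 where the list passed, and lists without a member past the threshold were given by their counts.

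The procedure was tested on simulated data, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale among 11625 genes with the spread of these arrays. The simulated noise was independent between genes and arrays, and no simulated array lay with another group. The rates below hold for such data and may not carry over to the real arrays, where several lay closer to another group. For ozone minus air it recovered 97% of the smaller and 100% of the larger changes on day 1 with 6.64% of calls false, 94% and 99% on day 2 with 7.21% false, and 97% and 100% at 18 h with 6.64% false. For the change of the ozone effect it recovered 84% and 100% from day 1 to day 2 with 4.66% false, and 86% and 97% from day 2 to 18 h with 4.19% false. Between the air groups it recovered 97% and 100%, with 6.19% false.

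Alternatives planned before the data were examined were quantile normalization, median centring, offsets of 1 and 64, no intensity filter and one at the 50th percentile, the mean of a gene's probe sets, all probe sets singly, eBayes without trend, array weights, the replicate number as a block, only the arrays of the groups compared, each array left out in turn, and the estimated correlation for lists. Added after the data were seen were fits without 2, 3 or 4 arrays that lay closer to another group, without both low-background arrays of day 1, and with the 3' to 5' beta-actin ratio as a covariate. Also added were the lists of both changes of the ozone effect and of the air groups with each array left out, and the estimated correlation for lists without those 2 or 3 arrays and, at 18 h, without each array. The number of genes past the threshold was also counted in 100 splits of the arrays for each contrast.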

Results

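Liver gene expression was measured in male Wistar Kyoto rats that breathed filtered air or ozone, an oxidant gas of polluted air, at 1 ppm. The rats were 10 weeks old and weighed 250 to 300 g. Each exposure lasted 6 h per day, for 1 day or for 2 days in a row. Livers were taken at the end of exposure on day 1 (6 arrays after air and 6 after ozone), at the end of exposure on day 2 (5 and 5), and 18 h after the end of exposure on day 2 (5 and 5). The 32 arrays thus formed 6 groups, and each of the 3 harvest times had its own air group. The labels do not say that each array held the liver of a different animal, so the p-values below measure the spread between these samples. The number of arrays in a group limits the precision of every comparison.

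The median probe-set intensity of an array lay between 147 and 161 units, so the arrays were of similar brightness. Probes that measure nonspecific binding had a median intensity of 54.3 on day 1 air replicate 2 and of 66.1 on day 1 ozone replicate 3, against 85.2 to 92.0 on the other arrays. The ratio of the 3' to the 5' beta-actin signal, a sign of RNA integrity, was 3.50 for ozone replicate 5 at 18 h and 2.16 to 2.89 for the others. No pair of arrays held identical values.

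On the first principal component, which held 37.0% of the variance, the 6 ozone arrays of day 1 lay farthest from most air arrays. Day 2 air replicate 5, at 12.7, lay next to the lowest of them, at 13.2. The second component held 15.4%. Several arrays lay closer to another group than to their own. The measure was the correlation across genes, centred on the mean of all arrays, between an array and the mean of the other arrays of a group (genes are not independent replicates). Day 2 air replicate 5 had r = -0.52 with its own group and r = 0.60 with day 2 ozone. Day 2 ozone replicate 5 had r = -0.25 with its own group and r = 0.66 with ozone at 18 h. At 18 h, air replicate 5 had r = 0.10 with its own group and r = 0.61 with day 1 air, and air replicate 1 had r = 0.26 with its own group and r = 0.70 with ozone at 18 h. Day 1 air replicate 5, day 2 air replicate 1 and day 2 air replicate 2 also lay closer to the other air group at the end of exposure than to their own. Counts without the first 3 or the first 4 of these arrays, chosen after the data were seen, stand beside the comparisons they enter. These arrays were chosen because they lay away from their own group. Leaving them out therefore tends by itself to widen the gap between groups and to narrow the spread. Larger counts, smaller p-values and higher correlations in those fits are not separate evidence for an ozone effect.

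**Figure D1:**
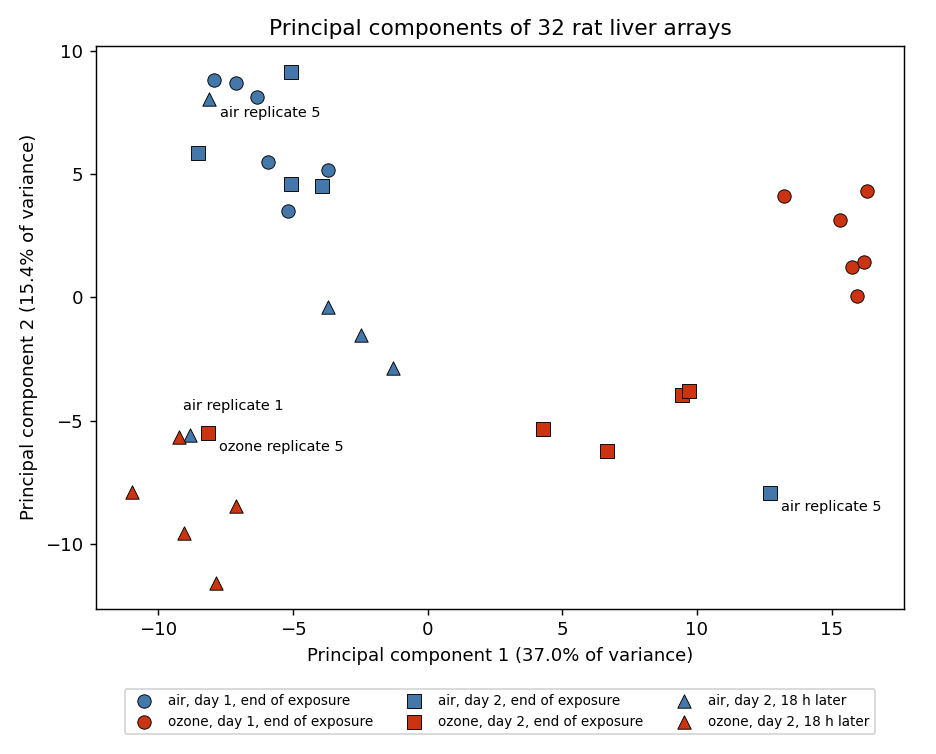
Principal component scores of the 32 arrays, 1 point per array, coloured by exposure and shaped by harvest time; the first component (horizontal) holds 37.0% and the second (vertical) 15.4% of the variance. The labelled points are the 4 arrays that lie among another group: day 2 air replicate 5 stands with the day 2 ozone arrays, day 2 ozone replicate 5 and air replicate 1 at 18 h stand with the ozone arrays at 18 h, and air replicate 5 at 18 h stands with the earlier air arrays.

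The first comparison set ozone against air at the end of exposure on day 1. Cxcl1, a chemokine that attracts neutrophils, rose 8.02-fold after ozone (log2 difference 3.00 ± 0.53, SE, n = 6 and 6, adjusted p = 5.5e-05), from a log2 level of 7.57 ± 0.57 (SD) to 10.58 ± 0.69. Got1, the cytosolic aspartate aminotransferase, rose 4.75-fold, and Sds, the serine dehydratase that turns serine into pyruvate, rose 3.71-fold. Rbm3, a cold-inducible RNA-binding protein, rose 3.38-fold, and Cdkn1a, the cell cycle inhibitor p21, rose 3.36-fold. The largest falls were those of Hsd17b2, which oxidises estradiol and testosterone (log2 difference -2.66 ± 0.34), Nrep (-1.87 ± 0.39), Ifgga2l1 (-1.80 ± 0.33), Ppp2r2b, a regulatory subunit of protein phosphatase 2A (-1.75 ± 0.20), and Gclm, the modifier subunit of the enzyme that limits glutathione synthesis (-1.73 ± 0.18). These are the largest changes among genes that met the naming rule. The rule itself required all 6 ozone arrays to lie on the same side of the air mean.

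Genes of fuel metabolism moved in both directions on day 1. Of all genes tested 29.5% passed at this time, so a list with a share of calls near that does not stand out by its count. Of 16 tested genes of amino acid catabolism and the urea cycle, 11 rose and 2 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.00041, and adjusted p = 0.72 with an estimated correlation). Asl, which cleaves argininosuccinate in the urea cycle, rose by 1.13 ± 0.14, Aass, the first enzyme of lysine breakdown, by 0.91 ± 0.11, and Nags by 0.51 ± 0.07. Of 18 genes of fatty acid oxidation and ketogenesis, 10 rose and 1 fell, both also when adjusted over the list alone (camera adjusted p = 0.0073, and adjusted p = 0.72 with an estimated correlation). Cpt1a and Cpt2, which carry fatty acids into mitochondria, rose by 0.93 ± 0.18 and 0.85 ± 0.15, while Bdh1, which makes the ketone body beta-hydroxybutyrate, fell by 0.45 ± 0.10. Of 19 genes of oxidative phosphorylation 8 rose and 0 fell, with the same numbers adjusted over the list alone, by small amounts such as 0.27 ± 0.06 for Uqcrfs1 and 0.26 ± 0.05 for Ndufs3 (camera adjusted p = 0.003, and adjusted p = 0.72 with an estimated correlation). Of 17 genes of cholesterol synthesis 1 rose and 9 fell, or 2 and 11 adjusted over the list alone (camera adjusted p = 0.0024, and adjusted p = 0.72 with an estimated correlation). Among them Msmo1 fell by 1.27 ± 0.25, Fdft1, squalene synthase, by 1.15 ± 0.17, and Srebf2, the transcription factor of the pathway, by 0.33 ± 0.06.

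Bile acid genes, NRF2 targets and growth hormone targets shifted downward as lists on day 1, with calls that were lost with an estimated correlation. Of 17 genes of bile acid synthesis and transport 1 rose and 11 fell, or 2 and 11 adjusted over the list alone (camera adjusted p = 0.00041, and adjusted p = 0.11 with an estimated correlation). Abcc2, an export pump of the bile canaliculus, fell by 0.87 ± 0.13, and Baat, which joins bile acids to amino acids, by 0.85 ± 0.09. Of 19 antioxidant targets of the transcription factor NRF2, 1 rose and 9 fell, or 2 and 11 adjusted over the list alone (camera adjusted p = 0.0073, and adjusted p = 0.72 with an estimated correlation). Gclc, the catalytic partner of Gclm, fell by 0.93 ± 0.13, and Cat, catalase, by 0.23 ± 0.05, while Srxn1, sulfiredoxin, rose by 0.30 ± 0.05. Of 15 targets of growth hormone and STAT5, 0 rose and 5 fell, or 0 and 6 adjusted over the list alone, among them Socs2 by 0.95 ± 0.18 and Igfals, a carrier protein of circulating IGF1, by 0.67 ± 0.16 (camera adjusted p = 0.02, and adjusted p = 0.72 with an estimated correlation). Their list no longer passed without air replicate 2 (adjusted p = 0.053).

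Of 17 interferon response genes 0 rose and 9 fell on day 1, with the same numbers adjusted over the list alone (camera adjusted p = 0.003, and adjusted p = 0.72 with an estimated correlation). Ifit2 fell by 0.53 ± 0.09, Mx1 by 0.53 ± 0.12 and Cxcl10 by 0.43 ± 0.11. The 11 markers of Kupffer cells and macrophages had a median log2 difference of -0.14, and 2 of them fell (1 adjusted over the list alone, camera adjusted p = 0.27). Lyz2, the lysozyme of macrophages, fell by 0.63 ± 0.09. The cell cycle list shifted upward, with 4 rises and 1 fall among 15 genes, also adjusted over the list alone (camera adjusted p = 0.031, and adjusted p = 0.72 with an estimated correlation). It no longer passed without air replicate 2 (adjusted p = 0.093), air replicate 4 (0.060) or ozone replicate 1 (0.066). Its members that moved most differ in what they do. Cdkn1a, which rose, stops the cycle, Ccnd1, cyclin D1, which drives entry into it, fell by 0.77 ± 0.09, and Rrm2, which makes deoxynucleotides, rose by 0.42 ± 0.07.

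The other 20 lists did not pass on day 1, though single members did. Adjusted p-values given with these lists are camera values of the lists, not of the genes named. Among 19 glucocorticoid-responsive genes 6 rose and 2 fell (6 and 3 adjusted over the list alone, adjusted p = 0.29), with Fkbp5, a chaperone partner of the glucocorticoid receptor, higher by 1.17 ± 0.17. Among 26 acute phase genes 4 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.29), with Stat3 higher by 1.12 ± 0.13 and Serpina3n by 0.34 ± 0.08. Among 15 circadian clock genes 3 rose and 5 fell (the same adjusted over the list alone, adjusted p = 0.66), with Bmal1 higher by 0.51 ± 0.08, and Nr1d2 lower, at -0.58 ± 0.12. Among 19 xenobiotic enzymes 4 rose and 7 fell (5 and 7 adjusted over the list alone, adjusted p = 0.52). Their median was -0.12 with a mean of 0.00, and Por, the electron donor of cytochromes P450, rose by 1.40 ± 0.23. Rises and falls numbered 2 and 7 of 18 for heat shock and the unfolded protein response, where Xbp1 fell by 0.67 ± 0.12 (2 and 8 adjusted over the list alone, adjusted p = 0.12, and 0.046 without ozone replicate 3). They numbered 1 and 6 of 18 for fatty acid and triglyceride synthesis (the same adjusted over the list alone, adjusted p = 0.18) and 5 and 1 of 14 for gluconeogenesis and fasting signalling, where Pck1 fell by 0.37 ± 0.06 (the same adjusted over the list alone, adjusted p = 0.27). For metallothionein and zinc handling they numbered 3 and 0 of 6 (the same adjusted over the list alone, adjusted p = 0.29), with Mt2A higher by 0.69 ± 0.21, and for glycolysis 3 and 3 of 10 (the same adjusted over the list alone, adjusted p = 0.81). For the integrated stress response they were 1 and 1 of 16 (1 and 0 adjusted over the list alone, adjusted p = 0.85), for immediate early genes 1 and 1 of 11 (0 and 1 adjusted over the list alone, adjusted p = 0.85), and for ribosomal proteins 1 and 1 of 13 (0 and 0 adjusted over the list alone, adjusted p = 0.27).

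Markers of other cell types gave few calls on day 1, and none of their lists passed. Falls numbered 3 of 11 endothelial markers (adjusted p = 0.52) and 2 of 9 cholangiocyte markers (adjusted p = 0.56), with 0 rises in each and the same numbers adjusted over the list alone. Of 6 neutrophil and monocyte markers 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.81). Of 11 lymphocyte markers 1 fell, also adjusted over the list alone (adjusted p = 0.69, median 0.00 with a test direction downward). Of 11 pancreas and adipose markers 1 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.76). Of 14 hepatic stellate cell and fibroblast markers 1 fell, and 0 adjusted over the list alone (adjusted p = 0.57). Of 5 erythroid markers 0 passed by either count (adjusted p = 0.57).

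In all, 3428 of 11625 genes passed on day 1 in limma (adjusted p under the threshold), 1520 higher and 1908 lower after ozone. Most changes were small, with a median size of 0.22 on the log2 scale, and 30 genes rose and 34 fell at least 2-fold. The count was 5691, 2619 higher and 3072 lower, over all probe sets singly. Without any single array it stayed between 3086 and 3498. The called genes include 1018 with several probe sets, and 27 of these had another probe set past the threshold in the opposite direction.

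**Figure D2:**
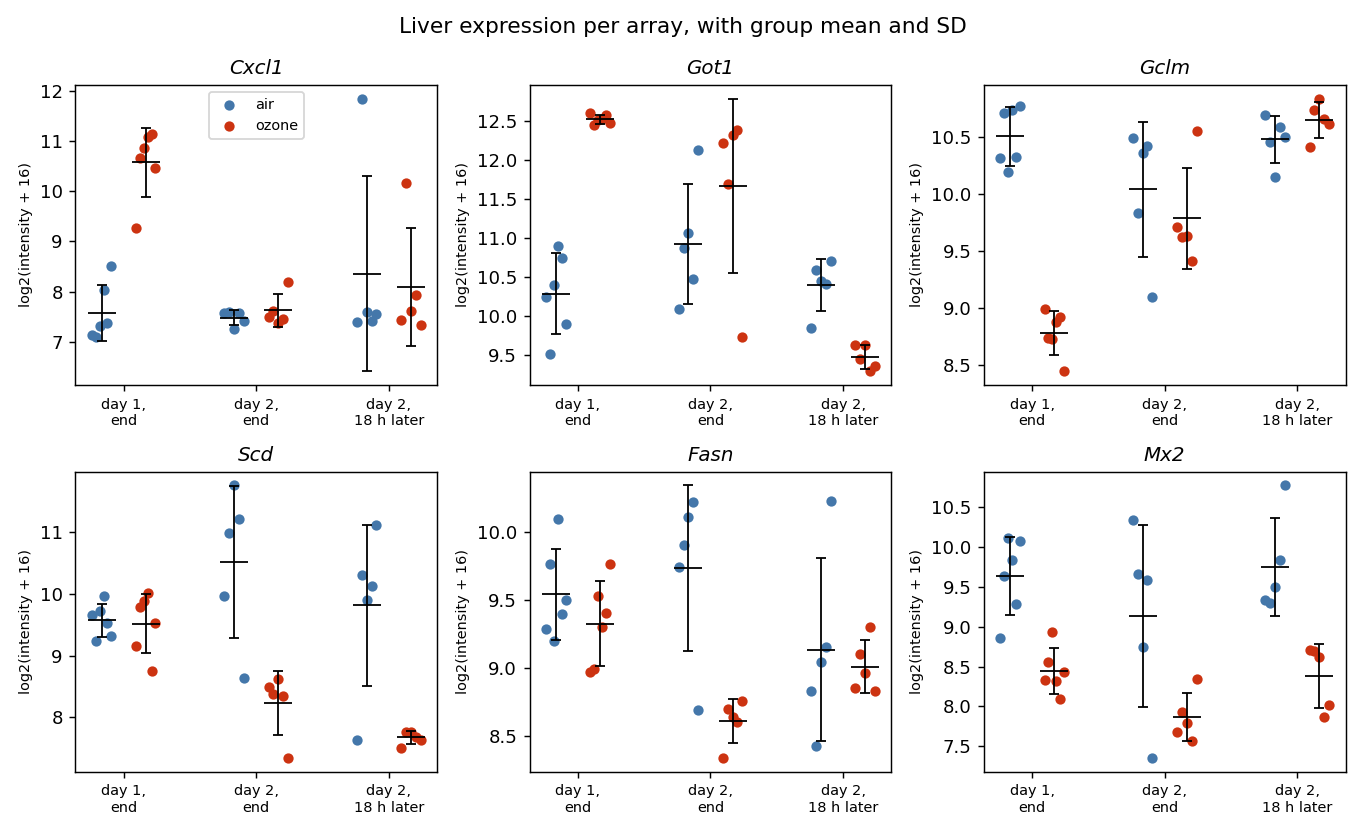
Expression of 6 genes on each of the 32 arrays, as log2(intensity + 16) on the vertical axis, by harvest time and exposure; points are arrays, and the long bars and whiskers are group means and SD. Cxcl1 in ozone arrays of day 1 averages 10.58 against 7.57 in air, and Scd in ozone arrays of day 2 averages 8.23 against 10.51 in air, with single air arrays of day 2 and of 18 h among the ozone values.

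The second comparison asked how ozone and air livers differed at the end of exposure on day 2. Scd, the desaturase that makes monounsaturated fatty acids, fell 4.83-fold (log2 difference -2.27 ± 0.45, n = 5 and 5, adjusted p = 0.025). Acly, which supplies acetyl-CoA for lipid synthesis, fell by 1.26 ± 0.29 and Fasn, fatty acid synthase, by 1.13 ± 0.25. Rcan1, an inhibitor of calcineurin, fell by 1.44 ± 0.33 and Ppp2r2b by 0.99 ± 0.22. The largest rises were those of the tight junction gene Cldn1 (1.10 ± 0.27), Atp1b1 (0.89 ± 0.21), Lgalsl (0.87 ± 0.18), and Eci1 (0.83 ± 0.20) and Ech1 (0.76 ± 0.19), which are isomerases that prepare unsaturated fatty acids for oxidation. These 10 genes are the largest changes that met the naming rule, which required all 5 ozone arrays to lie on the same side of the air mean.

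By list, 1 of 18 genes of fatty acid and triglyceride synthesis rose and 4 fell on day 2, or 3 and 11 adjusted over the list alone (camera adjusted p = 2.7e-07, and adjusted p = 0.28 with an estimated correlation). Fads2 fell by 0.90 ± 0.16, and Agpat2, an acyltransferase of triglyceride synthesis, rose by 0.48 ± 0.09. No cholesterol synthesis gene passed by either count, yet the list shifted downward, with a median of -0.23 over 17 genes (camera adjusted p = 3.3e-06, and adjusted p = 0.41 with an estimated correlation). Fatty acid oxidation shifted upward, with 1 rise and 0 falls among 18 genes, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.44 with an estimated correlation). Decr1, another enzyme of unsaturated fatty acid oxidation, rose by 0.41 ± 0.10, and Cpt2 had a difference of 0.54 ± 0.17 that did not pass. Of 14 genes of gluconeogenesis and fasting signalling 1 rose, Gpt, alanine aminotransferase, by 0.54 ± 0.13, or 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.032, and adjusted p = 0.48 with an estimated correlation). This list no longer passed without air replicate 1, 2 or 4 (adjusted p = 0.078, 0.081 and 0.053) or ozone replicate 1, 2 or 3 (0.053, 0.054 and 0.25). Amino acid catabolism shifted upward with 0 calls among 16 genes, or 6 rises adjusted over the list alone (camera adjusted p = 0.0044, and adjusted p = 0.49 with an estimated correlation). It no longer passed without air replicate 1 (adjusted p = 0.088) or ozone replicate 3 (0.056). Oxidative phosphorylation shifted upward too, with 0 calls among 19 genes, or 3 rises adjusted over the list alone (camera adjusted p = 0.0021, and adjusted p = 0.48 with an estimated correlation).

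Several further lists passed on day 2 without a member past the threshold over all genes. The 17 interferon response genes shifted downward, with a median of -0.29 and 9 falls adjusted over the list alone (camera adjusted p = 1.4e-10, and adjusted p = 0.28 with an estimated correlation). The 19 NRF2 targets shifted downward, with 5 falls adjusted over the list alone (camera adjusted p = 5.9e-05, and adjusted p = 0.28 with an estimated correlation). The 15 growth hormone and STAT5 targets did so with 4 falls adjusted over the list alone (camera adjusted p = 0.0044, and adjusted p = 0.28 with an estimated correlation), and the 17 bile acid genes with 5 (camera adjusted p = 0.0088, and adjusted p = 0.28 with an estimated correlation). The 26 acute phase genes shifted upward, with 1 rise adjusted over the list alone (camera adjusted p = 0.00091, and adjusted p = 0.41 with an estimated correlation). Beside these, the 11 Kupffer cell and macrophage markers shifted downward, with a median of -0.11 and 1 fall by both counts, Lyz2 by 0.40 ± 0.10 (camera adjusted p = 0.029, and adjusted p = 0.62 with an estimated correlation). They no longer passed without air replicate 1 or 2 (adjusted p = 0.64 and 0.13) or ozone replicate 4 or 5 (0.26 and 0.077).

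The other 17 lists did not pass on day 2, and adjusted p-values in this paragraph are camera values of lists, not of the genes named. Glycolysis had 2 falls among 10 genes, or 3 adjusted over the list alone, with Pklr, liver pyruvate kinase, lower by 0.89 and an SE of 0.17 (adjusted p = 0.055). The cell cycle list had 1 fall by both counts, Ccnd1, at -0.43 ± 0.10 (adjusted p = 0.064). Glycolysis passed without air replicate 1 or 4 or ozone replicate 3 or 4 (adjusted p between 0.025 and 0.036), and the cell cycle list without air replicate 1, 2 or 3 or ozone replicate 1 or 3 (0.027 to 0.043), both downward. The clock list had 1 rise, Cry1, a repressor of the clock, at 0.43 ± 0.09, or 3 rises and 1 fall adjusted over the list alone (adjusted p = 0.32). Lists without a call over all genes were the integrated stress response (1 rise adjusted over the list alone, adjusted p = 0.21), xenobiotic enzymes (3 rises and 1 fall, 0.25), neutrophil and monocyte markers (1 fall, 0.52, median 0.02 with a mean of -0.04) and glucocorticoid-responsive genes (1 rise, 0.81). Lists with 0 calls by both counts had adjusted p = 0.32 for ribosomal proteins, 0.43 each for heat shock genes, lymphocyte markers and pancreas and adipose markers, 0.44 for cholangiocyte markers and 0.52 for endothelial markers. For erythroid markers it was 0.6, for stellate cell markers 0.78, and for metallothionein and immediate early genes 0.88 each.

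On day 2, 82 genes passed in limma, 54 higher and 28 lower (76 and 63 with quantile normalization), with a median size of 0.36, and 1510 had an unadjusted p below the threshold against 581 expected by chance. The count was 2032 with array weights (1069 higher and 963 lower), 37 over all probe sets singly (24 and 13), 22 without a filter (14 and 8), 15 with the beta-actin ratio as a covariate (11 and 4) and 1 with only the groups compared. It also depended on single arrays. It was 977 without air replicate 5 and 506 without ozone replicate 5. It was 7, 3, 1 and 1 without air replicates 1 to 4, and 3, 22, 2 and 3 without ozone replicates 1 to 4, so no named gene stayed past the threshold in every such fit. Without the 3 arrays numbered 5 that lay closer to another group, 1532 genes passed, 734 higher and 798 lower, and all 82 were among them. The choice of the arrays left out favours a larger count in that fit. In that fit Got1 was higher by 1.54 (adjusted p = 1.5e-05), Cpt2 by 0.89 (8.3e-07) and Cdkn1a by 0.60 (0.046), against 0.75, 0.54 and 0.37 with all arrays. The lists that passed numbered 11, and Kupffer cell markers were no longer among them. With an estimated correlation, 2 then passed, NRF2 targets and growth hormone targets, each downward (adjusted p = 0.039).

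The third comparison set ozone against air 18 h after the end of exposure on day 2. The largest falls included 3 interferon-induced genes. Mx2 fell 2.58-fold (log2 difference -1.37 ± 0.35, n = 5 and 5, adjusted p = 0.045), Usp18, which limits interferon signalling, by 1.14 ± 0.25, and Oas1a by 1.02 ± 0.20. Scd fell 4.39-fold (-2.13 ± 0.45), and Mfsd2a, a transporter of lysophospholipids, by 1.38 ± 0.29. The largest rises were those of Akr1b7, an aldo-keto reductase (1.12 ± 0.20, 2.17-fold), Chka, choline kinase (0.89 ± 0.22), Fgf21, a fasting-induced liver hormone (0.76 ± 0.19), Id2 (0.73 ± 0.16) and Trim24 (0.71 ± 0.15). Here too the naming rule required all 5 ozone arrays to lie on the same side of the air mean for each of these 10 genes.

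Of 17 interferon response genes 0 rose and 7 fell at 18 h, or 0 and 13 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 5.7e-19, and adjusted p = 0.031 with an estimated correlation). The latter was 0.082 without air replicate 2 and 0.055 without ozone replicate 1, and it passed without each of the other 8 arrays of this time in turn. Beside them the 11 Kupffer cell and macrophage markers had a median of -0.24, with 0 calls by both counts (camera adjusted p = 2.7e-05, and adjusted p = 0.32 with an estimated correlation). Of 19 glucocorticoid-responsive genes 0 rose and 2 fell, or 0 and 7 adjusted over the list alone, with a median of -0.42 (camera adjusted p = 1.1e-11, and adjusted p = 0.031 with an estimated correlation). Klf9 fell by 0.51 ± 0.12 and Errfi1 by 0.36 ± 0.09, and Mt2A had a difference of -0.85 ± 0.23 that did not pass. The 6 genes of metallothionein and zinc handling shifted downward with 0 calls, or 2 falls adjusted over the list alone (camera adjusted p = 0.0065, and adjusted p = 0.031 with an estimated correlation). This list shares members with the glucocorticoid list, among them Mt2A, so the results of both lists are not separate. The 10 glycolysis genes shifted downward, with a median of -0.11 and 0 calls by both counts (camera adjusted p = 0.00021, and adjusted p = 0.02 with an estimated correlation). These 4 lists, the Kupffer markers aside, were those that passed with either correlation, but with the estimated one none of them passed without air replicate 2. There adjusted p was 0.12 for the glucocorticoid and metallothionein lists and 0.062 for glycolysis. The glucocorticoid list also missed the threshold without ozone replicate 1 (adjusted p = 0.055), and metallothioneins without air replicate 3 (0.083) or ozone replicate 1 (0.058).

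The calls of the other lists that shifted at 18 h were lost with an estimated correlation. Of 19 xenobiotic enzymes 2 fell, or 3 adjusted over the list alone, with Fmo1, a flavin monooxygenase, lower by 0.69 and an SE of 0.12, and Cyp1a1 by 0.60 with an SE of 0.15 (camera adjusted p = 7e-06, and adjusted p = 0.063 with an estimated correlation, or 0.047, 0.032 and 0.043 without air replicate 1, air replicate 5 and ozone replicate 5). Amino acid catabolism shifted downward, with 0 calls or 3 falls adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.34 with an estimated correlation). Gluconeogenesis did so with 0 calls or 2 falls adjusted over the list alone (camera adjusted p = 0.0017, and adjusted p = 0.25 with an estimated correlation). The cell cycle list had 1 fall by both counts, Ccnd1, at -0.40 ± 0.10 (camera adjusted p = 0.0063, and adjusted p = 0.32 with an estimated correlation). Oxidative phosphorylation (camera adjusted p = 0.009) and NRF2 targets (camera adjusted p = 0.016) shifted downward with 0 calls by both counts, and each had adjusted p = 0.45 with an estimated correlation. Cholesterol synthesis shifted upward, with a median of 0.15 and 0 calls or 2 rises adjusted over the list alone (camera adjusted p = 0.0065, and adjusted p = 0.53 with an estimated correlation). The mean score of this list, centred on all air arrays, was -0.16 in air at 18 h against 0.13 in air on day 2. The integrated stress response had 1 rise, Fgf21, which is also in the fatty acid oxidation list, or 4 adjusted over the list alone (camera adjusted p = 0.0071, and adjusted p = 0.19 with an estimated correlation). Heat shock and the unfolded protein response had 1 rise, Dnajc3, a chaperone of the endoplasmic reticulum, at 0.30 ± 0.07, or 2 adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.45 with an estimated correlation). None of these 3 upward lists passed without ozone replicate 2, at adjusted p = 0.053 for cholesterol synthesis, 0.11 for the integrated stress response and 0.054 for heat shock, and the 10 lists that then passed were all lower. Cholesterol synthesis was also lost without air replicate 1 (0.075), air replicate 2 (0.096) or ozone replicate 4 (0.083), and heat shock without air replicate 3 (0.11) or ozone replicate 1 (0.090). Of the downward lists, oxidative phosphorylation was lost without ozone replicate 2 (0.054), and NRF2 targets without air replicate 5 (0.26) or ozone replicate 1 (0.062).

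The other 15 lists did not pass at 18 h, and adjusted p-values given with them are camera values of lists, not of the genes named. Single members did in the clock list, where Cry1 rose by 0.58 ± 0.09 (2 rises adjusted over the list alone, adjusted p = 0.62), and among acute phase genes, where Apcs rose by 0.25 ± 0.04 (1 adjusted over the list alone, adjusted p = 0.56). They did so too among growth hormone targets, where A1bg rose by 0.21 ± 0.05 (1 adjusted over the list alone, adjusted p = 0.68, median -0.01 with a mean of 0.01), and endothelial markers, where Stab2 rose by 0.28 ± 0.07 (1 adjusted over the list alone, adjusted p = 0.055). Of pancreas and adipose markers Cela1 fell by 0.41 ± 0.09 (1 adjusted over the list alone, adjusted p = 0.053). In fatty acid oxidation Fgf21 was the 1 call, or 2 rises adjusted over the list alone (adjusted p = 0.41, median -0.01 with a mean of 0.01), and in fatty acid synthesis Scd was the 1 call, or 2 rises and 1 fall adjusted over the list alone (adjusted p = 0.24). Bile acid genes had 0 calls, or 2 falls adjusted over the list alone (adjusted p = 0.072, median 0.00 with a mean of 0.01), and neutrophil and monocyte markers 0, or 1 fall adjusted over the list alone (adjusted p = 0.055). Lists with 0 calls by both counts were stellate cell markers (adjusted p = 0.23), immediate early genes (0.57), ribosomal proteins (0.61), cholangiocyte markers (0.89), lymphocyte markers (0.94) and erythroid markers (0.97, median 0.03 with a test direction downward). Without air replicate 5, fatty acid oxidation (0.0035), bile acid genes (0.020), neutrophil and monocyte markers (0.037) and pancreas and adipose markers (0.014) passed downward and endothelial markers (0.021) upward. Bile acid genes (0.037) and endothelial markers (0.039) also passed without air replicate 1, endothelial markers without ozone replicate 1 (0.0057), and immediate early genes upward (0.014) and fatty acid synthesis downward (0.044) without air replicate 2. Neutrophil and monocyte markers (0.0094) and pancreas and adipose markers (0.030) passed without air replicate 4, and the latter without ozone replicate 3 (0.048) or 5 (0.014).

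At 18 h 136 genes passed in limma, 100 higher and 36 lower (93 and 74 with quantile normalization, 45 and 29 with median centring), with a median size of 0.32. The count was 614 with array weights (429 higher and 185 lower), 33 with the beta-actin ratio as a covariate (20 and 13) and 1 with only the groups compared. Without air replicate 1, which lay closer to the ozone arrays of this time, 411 passed. The count was 53, 37, 32 and 86 without air replicates 2 to 5, and 42, 34 and 65 without ozone replicates 3 to 5. Akr1b7, Apcs, Cry1, Fmo1 and Oas1a passed in every such fit, and the other 18 named genes past the threshold were lost without at least 1 array. Without the 3 arrays numbered 5, 238 genes passed, 176 higher and 62 lower, and 118 of the 136 were among them. Without air replicate 1 as well, 576 passed, 432 higher and 144 lower, and 131 of the 136 were among them, a count that the choice of arrays also favours. In that last fit Mt2A was lower, at -1.36 (adjusted p = 3.4e-06), and Per2, a clock gene, higher by 0.73 (adjusted p = 0.00011). The interferon and glucocorticoid lists passed without the 3 arrays (adjusted p = 1.7e-17 and 5e-14), and both also with an estimated correlation (adjusted p = 0.024 each).

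**Figure D3:**
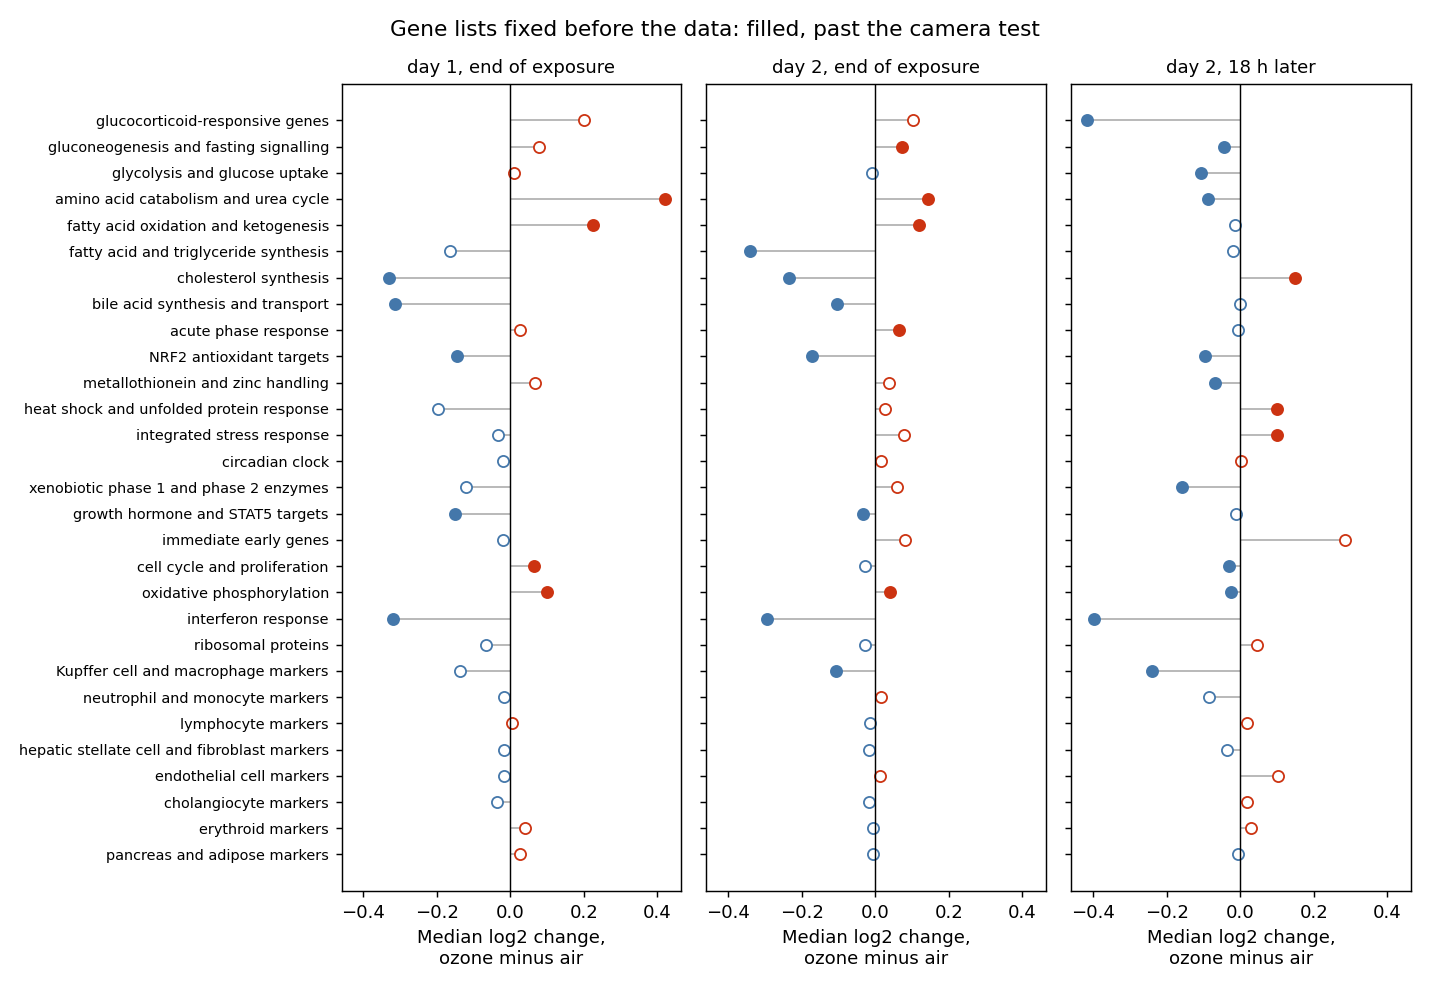
Median log2 difference, ozone minus air, of the tested members of each of 29 gene lists fixed before the data were examined, with 1 panel per harvest time; filled points passed the camera test with the preset correlation, and red is higher and blue lower. Amino acid catabolism has a median of 0.42 on day 1, and the interferon response list lies at -0.32, -0.29 and -0.40 at the 3 times.

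Tests of the difference between the ozone effects asked whether the response changed from day 1 to day 2. The effect on Cxcl1 was smaller on day 2 (difference of effects -2.86 ± 0.78, adjusted p = 0.028), as was that on Cdkn1a (-1.38 ± 0.27). Fabp5, a fatty acid binding protein (-1.07 ± 0.22), and Pnpla2, the lipase that starts triglyceride breakdown (-0.998 ± 0.22), also had lower effects on day 2. Differences of effects are signed throughout. A lower effect can thus be a smaller rise or a larger fall, and a higher effect can be a smaller fall. The difference for Scd (-2.22 ± 0.61) was close to the size of its fall on day 2, so little of that fall was present on day 1. The effect was higher on day 2 for Osgin1, an oxidative stress-induced gene (1.497 ± 0.45), Gclm (1.47 ± 0.27), Fabp7 (1.42 ± 0.25), the sialyltransferase St3gal6 (1.20 ± 0.23) and Ptger3, a prostaglandin E2 receptor (1.04 ± 0.18). For Gclm this was a smaller fall, since its fall on day 1 exceeded the difference. Without the 3 arrays, Cxcl1 (-3.02, adjusted p = 0.054) and Osgin1 (1.00, adjusted p = 0.16) no longer passed.

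By list, the effect on day 2 was lower than on day 1 for amino acid catabolism (median difference -0.24, camera adjusted p = 0.018) and the cell cycle (-0.10, 0.0012). It was higher for bile acid genes (0.25, 0.018) and for heat shock and the unfolded protein response (0.17, 0.042). None of these 4 passed with an estimated correlation (adjusted p = 0.95, 0.51, 0.51 and 0.95). In the fit without the 3 arrays, amino acid catabolism (adjusted p = 0.14) and heat shock genes (0.20) no longer passed at the preset correlation, bile acid genes (0.034) and the cell cycle (0.0023) did, and the effects on fatty acid synthesis (0.0023) and interferon response genes (0.034) were then lower on day 2. With an estimated correlation none of these passed in that fit, at adjusted p = 0.86 for interferon response genes, amino acid catabolism and heat shock genes and 0.38 for the other 3. With all arrays but 1, bile acid genes were lost without day 1 air replicate 2 (adjusted p = 0.085) and heat shock genes without any of 12 arrays (0.051 to 0.20). Amino acid catabolism was lost without day 1 air replicate 1 (0.059), day 1 ozone replicate 1 (0.070), day 2 air replicate 3 (0.055) or day 2 ozone replicate 5 (0.11), and fatty acid synthesis passed without day 2 air replicate 5 (0.033). In limma 592 genes differed between the effects, 364 with a higher and 228 with a lower effect on day 2. The count was 948 with array weights (552 and 396), 916 over all probe sets singly (526 and 390) and 340 without both low-background arrays of day 1 (195 and 145). It was 892 without day 2 air replicate 1, 394 without air replicate 5 and 295 without ozone replicate 5 of that day. Without the 3 arrays it was 262, 217 of them among the 592. The call of Scd was lost without day 2 air replicate 2, 3 or 4 or ozone replicate 5, and that of Osgin1 without any of 15 arrays in turn.

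From day 2 to 18 h later, 1 gene differed in its ozone effect in limma, Phyh, which starts the breakdown of branched fatty acids (-0.59 ± 0.10, adjusted p = 0.036), and 1009 genes had an unadjusted p below the threshold against 581 expected. The count was 216 without day 2 air replicate 5, 82 without day 2 ozone replicate 5, 16 without air replicate 1 of 18 h and 5 without its air replicate 5, and 997 without the 3 arrays numbered 5. It was 0 without any of 14 other arrays in turn, and also with the mean of probe sets, all probe sets singly, the beta-actin ratio or only the groups compared, and 1047 with array weights (603 higher and 444 lower). By list the effect was lower at 18 h for glucocorticoid-responsive genes (median difference -0.42, camera adjusted p = 2e-08), amino acid catabolism (-0.25, 2.1e-07), xenobiotic enzymes (-0.22, 1.5e-06) and fatty acid oxidation (-0.19, 0.00046). It was also lower for gluconeogenesis (-0.18, 5.2e-06), oxidative phosphorylation (-0.09, 1.5e-06), acute phase genes (-0.06, 0.00087) and metallothioneins (-0.06, 0.027). It was higher for cholesterol synthesis (0.40, 3.2e-09) and fatty acid synthesis (0.19, 0.00087). The air groups contributed to several of these differences, as list scores centred on all air arrays show. From day 2 to 18 h the mean score of cholesterol synthesis went from 0.13 to -0.16 in air and -0.13 to 0.03 in ozone. For fatty acid synthesis it went from 0.10 to -0.15 in air and -0.37 to -0.28 in ozone. For fatty acid oxidation it went from -0.08 to 0.11 in air and 0.06 to 0.12 in ozone. None of these 10 lists passed with an estimated correlation, with adjusted p = 0.094 for glucocorticoid-responsive genes, xenobiotic enzymes, gluconeogenesis and metallothioneins, 0.18 for amino acid catabolism, 0.21 for cholesterol synthesis and oxidative phosphorylation, 0.32 for fatty acid synthesis, and 0.34 for the other 2. Metallothioneins no longer passed at the preset correlation in the fit without the 3 arrays (adjusted p = 0.095), and NRF2 targets (2.7e-05), growth hormone targets (0.002) and heat shock genes (0.015) then passed with a higher effect at 18 h. With an estimated correlation none passed in that fit, at adjusted p = 0.088 for NRF2 and growth hormone targets and 0.41 for heat shock genes. Of the 10 lists, metallothioneins were lost without day 2 air replicate 2 or 5 or air replicate 2 or 3 of 18 h (adjusted p between 0.055 and 0.071), and acute phase genes without air replicate 2 of 18 h (0.11). A further 6 lists passed without at least 1 array, interferon response genes (without 8 arrays) and Kupffer cell markers (2) with a lower effect at 18 h, and growth hormone targets (8), NRF2 targets (2), heat shock genes (1) and ribosomal proteins (1) with a higher one.

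Livers of rats that breathed only air were compared between 18 h after day 2 and the end of day 2, which differ in time of day and in time since handling. The largest rises at 18 h included 3 heat shock genes. Hsph1 rose by 0.75 ± 0.13 (adjusted p = 0.01), Hspb1 by 0.61 ± 0.11 and Hsp90ab1 by 0.46 ± 0.09, followed by Chd9 (0.40 ± 0.09) and Plpp2 (0.37 ± 0.07). Falls were small, at -0.28 ± 0.05 for Lrp6, -0.28 ± 0.06 for Pdlim5, -0.24 ± 0.05 for the organic anion transporter Slco2b1 and -0.21 ± 0.04 for Ccdc77. Of the clock genes, Dbp had a difference of -0.62 ± 0.26 (adjusted p = 0.41) and Nr1d1 one of -0.33 ± 0.11 (adjusted p = 0.28), and neither passed. In limma 14 genes passed, 10 higher and 4 lower (5 and 1 with median centring), and 1094 had an unadjusted p below the threshold against 581 expected. The count was 693 with array weights (440 and 253), 39 with quantile normalization (26 and 13), 22 with the 50th percentile filter, 8 without a filter, 6 with the mean of probe sets and 0 with only the groups compared. It was 32, 7, 8 and 0 without day 2 air replicates 1 to 4, and 7, 0, 5 and 83 without air replicates 1, 2, 4 and 5 of 18 h. Without the 3 arrays 331 passed, 124 higher and 207 lower, with all 14 among them, and Dbp (-0.98) and Nr1d1 (-0.44) then passed with adjusted p = 0.023 each.

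The ozone effects of the 3 times rest on separate air groups, so they can be set against each other across genes, which are not independent replicates. Between day 1 and day 2 the log2 differences of 11625 genes had r = 0.60 (Spearman 0.44). Of the genes past the threshold at both times 22 were higher and 21 lower at both, against 7.06 and 4.60 expected for independent lists, and 0 were opposite against 12.5 expected. Of the genes past the threshold on day 1, 80.0% had the same sign on day 2. Between day 1 and 18 h after day 2 the correlation was r = -0.16 (Spearman -0.12), and 37 genes passed in opposite directions against 21.1 expected, while 5 were higher and 12 lower at both against 13.1 and 5.91 expected. Between day 2 and 18 h later it was r = 0.24 (Spearman 0.16), with 6 genes higher and 5 lower at both against 0.46 and 0.09 expected. Without the 3 arrays these correlations were 0.74, -0.24 and -0.02, though the choice of these arrays bears on the values. The first pair of times then shared 521 rises and 637 falls against 102 and 144 expected, with 11 opposite against 242. The pair of day 1 and 18 h then had 106 opposite calls against 40.2 expected, and 9 higher and 19 lower at both against 24.3 and 11.2. The pair of day 2 and 18 h had 39 opposite calls against 16, and 22 higher and 29 lower at both against 11.1 and 4.26.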

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

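The counts over other splits of the arrays, the draws of 4 arrays per group and the tests of macrophage markers at each single time were planned before their results were seen, and the other tests of explanations in this part were chosen after.

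The number of genes past the threshold was set against other splits of the same arrays. Chance can be excluded for ozone against air on day 1, where 1 of 100 splits, the real one, gave 3428 genes and the highest other 1000. At 18 h after day 2 the real split also ranked first (1 of 100), but with 136 genes against 132 in the highest other. That margin is too narrow to exclude chance firmly, and the count was 32 without air replicate 4. For the change of the ozone effect from day 1 to day 2, 3 of 100 splits gave at least 592 genes, with 1700 in the highest other. Those splits redrew ozone and air within each time, which removes the day 1 effect too. They cannot decide whether the effects of day 1 and day 2 were equal, and a structure of the samples also bears on that count. Chance could not be excluded for ozone against air on day 2, where 9 of 100 splits gave at least 82 genes and the highest other 1909. The same holds for the change of the effect from day 2 to 18 h later (7 of 100, with 1 gene and 1138 in the highest other), and for the air groups (11 of 100, with 14 genes and 529 in the highest other). Such splits again point to a structure of the samples that the groups do not give. On day 2, 8 other splits gave as many genes, and 5 of them exchanged the 2 arrays numbered 5.

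The first pattern is that 3 arrays numbered 5 correlate with another group more than with their own (group means below are taken without these 3 arrays), as do 6 of the other 29 arrays, among them air replicate 1 of 18 h (0.21 with its own group and 0.70 with 18 h ozone) and day 2 air replicate 1 (0.38 and 0.66 with day 1 air). The 3' to 5' beta-actin ratios of the 3 arrays were 2.58 (day 2 air), 2.85 (day 2 ozone) and 2.47 (18 h air). Their nonspecific probes read 91.2, 89.2 and 91.8 units. Both measures lay within the range of the other arrays, which argues against degraded RNA or a shifted background in these 3. Low quality of another kind could not be decided. The lowest of their highest correlations with any group is 0.659, and the other arrays have a median of 0.611 with their own groups. A highest value over all groups is there set against a value with 1 group, so the measures are unlike. Each of the 3 did resemble some group about as closely as a typical array resembles its own. An exchange of labels between the day 2 air and ozone arrays numbered 5 is argued against, since that ozone array has a correlation of 0.0998 with the other day 2 air arrays, which have at least 0.384 with each other's mean. A rotation of labels among day 2 air, day 2 ozone and 18 h air cannot be told apart, since 2 of the 3 arrays have their highest correlation with the group it predicts (0.66 with day 2 ozone and 0.70 with day 2 air, where 6 of 25 arrays of other groups also reach that group's range), while day 2 ozone replicate 5 has 0.33 with 18 h air, a range that all 5 ozone arrays of 18 h reach too, and 0.66 with 18 h ozone, which leaves the test undecided. The rotation would not account for the other 6 arrays, no biological explanation was tested, and variation between animals and other handling errors stay open.

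The second pattern is that many more genes passed on day 1 (3428) than on day 2 (82). A hidden effect of equal size, masked by the arrays numbered 5, could not be decided as the whole cause. Without the 3 arrays 262 genes still differed between the effects, but the choice of these arrays favours smaller p-values in that fit. No splits of the arrays were counted for it. The larger number of arrays on day 1 is argued against, since the lowest of 100 draws of 4 arrays per group on day 1 gave 2534 genes (median 2860), above the 1532 of day 2 without the 3 arrays. What stays open, as untested, is a biological difference between a first and a repeated exposure, which the design names. Part of the gap in counts may still come from these arrays, since the day 2 count is 1532 without them, a count that their choice favours.

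The third pattern is that interferon response genes were lower after ozone, with a difference of list scores of -0.350 on day 1 (exact permutation p = 0.00433, adjusted 0.0357), -0.414 on day 2 (0.0556, adjusted 0.125, which does not pass) and -0.495 at 18 h (0.00794, adjusted 0.0357). A single array as the cause at 18 h is argued against, since the score difference stayed between -0.566 and -0.375 with each array left out in turn (highest exact permutation p = 0.0159), although the list call with an estimated correlation was lost without 2 of the 10 arrays (highest adjusted p = 0.0816). Over the 3 times together, the interferon score fell further than the macrophage score by a mean of -0.245 (permutation p = 0.00109, and -0.241 with p = 0.00073 without the 3 arrays). This argues against a loss of macrophages as the whole cause only if such a loss would lower both scores equally, which was not tested. At the single times that cause cannot be told apart, with -0.189 on day 1, -0.279 on day 2 and -0.266 at 18 h (adjusted exact p = 0.115, 0.0952 and 0.0952, few arrays). Of the 11 macrophage markers, 8 were lower after ozone on day 1, 9 on day 2 and 9 at 18 h, so most moved the same way as the interferon genes. Few had a difference at least as low as that of the interferon score. These were 2 on day 1 (Lyz2 at -0.63 with limma adjusted p = 3.8e-06 and Cd5l at -0.36), 0 on day 2 (Lyz2 at -0.40) and 1 at 18 h (Cd5l at -0.52, with Lyz2 at 0.01). The bright genes Clec4f (10.44 in air at 18 h, with differences of -0.20, -0.25 and -0.38 at the 3 times) and C1qa (9.66, with -0.19, -0.16 and -0.30) fell less. The interferon list shares 0 genes with other lists, and lymphocyte scores differed by -0.0255, -0.0164 and 0.0226. What stays open is a lower interferon response to ozone, as a hypothesis found and tested on the same arrays, and a part played by fewer macrophages. Where the markers understate a loss of cells, that part could be larger.

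Among the named genes, 36 of 360 pairs of gene and group had 1 array far from the others, against 18 expected since chance gives about 1 in 20. The values are log2 differences from the mean of the group's other arrays. Day 2 ozone replicate 5 had 8 of them, at -2.43 for Got1, 2.11 for Osgin1, -1.11 for Scd, 1.03 for Fabp7, 0.96 for Gclm, 0.71 for Cxcl1, -0.48 for Agpat2 and 0.42 for Lyz2. Day 2 air replicate 5 had 6, at -2.21 for Rcan1, 1.27 for Atp1b1, -1.13 for St3gal6, 0.79 for Pnpla2, 0.48 for Cdkn1a and 0.42 for Hadhb. Its score on the first principal component was 12.7, also far from its group, as was that of day 1 ozone replicate 1 at 13.2. Air replicate 1 at 18 h had 4, at 1.12 for Chka, -0.67 for Cyp1a2, 0.64 for Cry1 and -0.47 for Cela1.

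Further arrays at 18 h with such values were air replicate 5 (Ifit3 at 0.43 and Fgf21 at -0.37), ozone replicate 2 (Mfsd2a at 0.67 and Cry1 at -0.24) and ozone replicate 5 (Trim24 at -0.64 and Id2 at -0.44). On day 1 they were ozone replicate 1 (Cxcl1 at -1.57 and Serpina3n at -0.38), ozone replicate 4 (Cdkn1a at -1.34), ozone replicate 2 (Aass at -0.32), ozone replicate 3 (Xbp1 at 0.14) and ozone replicate 6 (Fabp7 at -0.45, Cpt2 at -0.39 and Col1a1 at -0.097). In day 1 air they were replicate 2 (Mmp8 at -0.24), replicate 5 (Stab2 at 0.35) and replicate 6 (Myc at 0.52 and Rps2 at 0.056).

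The ozone effect differed between day 1 and day 2, in limma's test of the difference, for 23 of the genes named in the text. With the sign kept, so that a larger fall counts as lower, it was lower on day 2 for Cxcl1 (-2.86), Scd (-2.22), Cdkn1a (-1.38), Fabp5 (-1.07), Pnpla2 (-0.998), Stat3 (-0.92), Asl (-0.74), Rrm2 (-0.55) and Slc39a14 (-0.53). It was higher on day 2 for Osgin1 (1.497), Gclm (1.47), Fabp7 (1.42), St3gal6 (1.20), Ptger3 (1.04), Gclc (0.87), Baat (0.60), Hspb1 (0.56), Hsp90ab1 (0.47), Dnajc3 (0.45), Chd9 (0.44), Epcam (0.40), Pdia4 (0.40) and Pck1 (0.38). From day 2 to 18 h later it differed for Phyh (-0.59).

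Median differences of lists past the camera test of the change from day 1 to day 2 were -0.24 for amino acid catabolism, 0.25 for bile acid genes, 0.17 for heat shock genes and -0.10 for the cell cycle. From day 2 to 18 h later they were -0.42 for glucocorticoid response, 0.40 for cholesterol synthesis, -0.25 for amino acid catabolism, -0.22 for xenobiotic enzymes, -0.19 for fatty acid oxidation and 0.19 for fatty acid synthesis. They were -0.18 for gluconeogenesis, -0.086 for oxidative phosphorylation, -0.062 for acute phase genes and -0.059 for metallothioneins, and none of these lists passed with an estimated correlation. Probe sets without a single gene in the annotation enter no comparison above except the counts over all probe sets singly. Of 7700 such probe sets, 1404 passed on day 1 (730 higher and 674 lower after ozone), 6 on day 2 (6 higher and 0 lower) and 17 at 18 h after day 2 (14 higher and 3 lower).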

How the results depend on the processing

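The fits without 2, 3 or 4 arrays, without both low-background arrays and with the beta-actin ratio were chosen after the data were seen. No named gene reversed direction under any alternative run, but the balance of calls turned for 3 contrasts. Day 2 had 54 higher and 28 lower genes, against 480 and 497 without air replicate 5, 726 and 754 without 2 arrays and 734 and 798 without 3. The air groups had 10 and 4, against 9 and 10 without day 2 air replicate 5, 28 and 29 without 2 arrays, 124 and 207 without 3 and 113 and 193 without 4. The change from day 2 to 18 h had 0 and 1, against 603 and 444 with array weights, 480 and 338 without 2 arrays, 625 and 372 without 3 and 755 and 377 without 4, and it also turned without day 2 air replicate 5 (140 and 76) and without air replicate 1 (9 and 7) or 5 (3 and 2) of 18 h. Offsets of 1 and 64 and eBayes without trend kept every count of genes within 1.5 times of the reported one, and no scaling moved the median of all genes by more than 0.02. For ozone against air on day 1 the count of 3428 lay between 2751 and 3674 in all alternatives but all probe sets singly (5691, where more features are tested).

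For ozone against air on day 2 (82 genes) the count was 139 with quantile normalization, 22 without a filter, 2032 with array weights, 37 over all probe sets and 1 with only the groups compared. It was 15 with the beta-actin ratio, 1480 without both day 2 arrays numbered 5 and 1532 without 3 arrays. At 18 h (136 genes) it was 74 with median centring, 614 with array weights, 1 with only the groups compared, 33 with the beta-actin ratio, 238 without 3 arrays and 576 without 4. For the change from day 1 to day 2 (592) it was 948 with array weights, 916 over all probe sets, 237 without 2 arrays, 262 without 3 and 340 without both low-background arrays. For the change from day 2 to 18 h (1 in limma, with 1009 at an unadjusted p below the threshold) it was 0 with the mean of probe sets, all probe sets, only the groups compared or the beta-actin ratio. It was 1047 with array weights, 818 without 2 arrays, 997 without 3 and 1132 without 4. Between air groups (14) it was 39 with quantile normalization, 6 with median centring, 8 without a filter, 22 with the 50th percentile filter, 6 with the mean of probe sets and 693 with array weights. There it was 0 with only the groups compared, 57 without 2 arrays, 331 without 3 and 306 without 4. With an estimated correlation 0 lists passed on day 1, 0 on day 2 and 4 at 18 h. On day 2 that number was 0 without 2 arrays and 2 without 3, and at 18 h it was 5 without 3. With only the groups compared, the spread came from fewer arrays and from those groups alone. On day 1 the count was then 3254, against 3428 with all groups. The counts of 82 on day 2 and 136 at 18 h, each 1 in that fit, thus rest on a spread shared with other groups. Whether fewer arrays or a different spread lowered them was not tested. For the other changes the cause was not tested either.

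The replicate numbers do not pair the arrays. Deviations of same-numbered arrays correlated between -0.40 and 0.02 on day 1, -0.58 and -0.02 on day 2, and -0.33 and 0.26 at 18 h, where 1 array correlated best with its own number. With the number as a block the counts were 3 on day 2 (2 higher and 1 lower), 35 at 18 h (18 and 17), 75 (42 and 33) and 0 for the changes of the effect and 1 between air groups, and 2751 on day 1. Under the block 52 calls of named genes, each a pair of gene and contrast, were lost and 1 was gained.

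With each array left out in turn, counts of genes ranged from 3086 to 3498 on day 1, 1 to 977 on day 2 and 32 to 411 at 18 h. They ranged from 295 to 892 and 0 to 216 for the changes of the effect, and 0 to 83 between air groups. Lists past the test ranged from 7 to 10, 11 to 13 and 10 to 18, and 7 of the 9 lists of day 1, 9 of the 12 of day 2 and 9 of the 14 of 18 h passed in every such fit. Over these fits the call of a named gene stayed the same in 1619 cases, was lost in 388 and gained in 23. Besides the block, calls of named genes, counted as pairs of gene and contrast, were lost with only the groups compared (57), with the beta-actin ratio (32), without a filter (20), with median centring (18), with the mean of probe sets (13), without both low-background arrays (8), with quantile normalization (6), without 3 arrays (5), without 2 (2), without 4 (2), without trend (2), with array weights (1) and with the offset of 64 (1). Such calls were gained with array weights (23), without 3 arrays (16), 4 (11) or 2 (7), with the 50th percentile filter (4), with quantile normalization (3), and with the mean of probe sets, the beta-actin ratio or only the groups compared (1 each). Signal over background limits dim genes, since the nonspecific probes alone read 54.3 to 92.0 units against array medians of 147 to 161.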

Other observations

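These values were chosen after they were seen. Between the air groups, whole lists shifted from the end of day 2 to 18 h later besides the single genes above. Of 29 lists, 9 passed, 6 upward and 3 downward, and 0 with an estimated correlation. Cholesterol synthesis genes shifted downward, with a median log2 difference of -0.26 (limma camera adjusted p = 1.4e-07, and adjusted p = 0.68 with an estimated correlation) and 0 of 17 genes past the threshold, or 2 falls adjusted over the list alone. Fatty acid synthesis genes also shifted downward (median -0.20, adjusted p = 0.00096, and adjusted p = 0.68 with an estimated correlation), with 0 calls among 18 genes by both counts. Fatty acid oxidation genes shifted upward (0.14, adjusted p = 0.00096, and adjusted p = 0.71 with an estimated correlation), with 0 calls among 18 or 2 rises adjusted over the list alone. Heat shock and unfolded protein response genes did so too (0.10, adjusted p = 0.00074, and adjusted p = 0.68 with an estimated correlation), with 2 rises among 18, or 4 adjusted over the list alone. These 4 lists passed without each of the 10 arrays in turn at the preset correlation.

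The other 5 lists did not pass in every such fit. Xenobiotic enzymes shifted upward (median 0.03, adjusted p = 0.0097, and adjusted p = 0.68 with an estimated correlation), but not without air replicate 4 of 18 h (adjusted p = 0.11). Amino acid catabolism shifted downward (-0.07, adjusted p = 0.028, and adjusted p = 0.82 with an estimated correlation), but not without day 2 air replicate 3 (0.10) or 5 (0.25) or air replicate 3 of 18 h (0.12). The other 3 shifted upward, each with adjusted p = 0.82 with an estimated correlation. Interferon response genes (0.12, adjusted p = 0.034) were lost without air replicates 3 and 5 of either time, 1 at a time (0.051 to 0.85). Endothelial markers (0.03, adjusted p = 0.038) were lost without day 2 air replicate 1 or 4 or air replicate 1, 3 or 5 of 18 h (0.051 to 0.15). Acute phase genes (0.06, adjusted p = 0.038) were lost without day 2 air replicate 2, 3 or 4 or air replicate 2 or 3 of 18 h (0.051 to 0.99), with a test direction downward without air replicate 2 of 18 h. A further 7 lists passed only without at least 1 array.

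Cxcl1 was high on single arrays 18 h after day 2 in both exposures. Its log2 level was 11.84 on air replicate 2 and 10.15 on ozone replicate 2, against 7.33 to 7.92 on the other 8 arrays of that time. On the same air array Stat3 had its highest level of that time, at 10.6.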
